A study of Mus musculus with 4 samples.

How the data were processed

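The series holds RNA sequencing of macrophages sorted from bone marrow and spleen of normal and T-ALL C57BL/6J mice, 4 libraries in all. Per the labels' protocols, total RNA was extracted with a Qiagen RNeasy kit and made into libraries by standard Illumina protocols; the sort's markers, the number and the sex of the mice are not given in the sources used here. Groups were taken from the sample titles, and each group has 1 library.

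Each library has a deposited table with 1 line per gene. Per the file headers, it gives the counts of uniquely mapped reads, the gene's length, its coverage, its RPKM, an NCBI Gene ID, a symbol and annotation. The deposited counts are whole numbers that sum to the total in the header, and genes without a read have no line, so they were set to 0. The deposited RPKM (reads scaled by the listed length and by that total) was recomputed from the counts and lengths to within 9.2e-06%. The aligner, the counting rule, the genome build and the annotation are not given in the sources used here, so no coordinates are reported. Symbols are those of the files, including older ones such as Emr1 (now Adgre1), Chi3l3 (now Chil3) and Igj (now Jchain). A spreadsheet had turned 23 symbols into dates, and these were restored through the Gene ID from a RefSeq gene table of the GRCm38.p6 assembly, in which 16951 of the 17008 Gene IDs were found. For 30 genes the length differed between files; the highest level among these was 5.58 CPM.

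The main unit is CPM, a gene's reads relative to the library's total, computed from the counts on library sizes scaled by TMM (edgeR 4.0.16, R 4.3.3), with factors of 1.00 for normal bone marrow, 0.991 for T-ALL bone marrow, 0.996 for normal spleen and 1.01 for T-ALL spleen. Totals ran from 8979385 to 9809676 reads, 1 read was worth 0.102 to 0.112 CPM, and the 10 most abundant genes took 4.78% to 6.30% of a library. Other computation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

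With 1 library per group no count model was fitted and no p-value computed. A gene was counted as higher or lower by a size rule, at least 2-fold on log2(CPM + 1) with 10 CPM or more in the higher library. Log2 folds are on that scale, which understates the change of low genes. Folds written as such are ratios of CPM without the pseudocount, with exact binomial 95% intervals from the pair of counts. Against 0 reads, a fold is a lower bound from a floor of 3 reads per library. Intervals and floors cover counting error only, and not the spread between animals. They treat reads as independent, and reads copied by PCR are not independent molecules, so they can be too narrow even for counting error. Reads of near-identical genes (haemoglobins, Ear, Stfa, Hspa1a and Hspa1b, MHC and NK receptor families) are uncertain, because reads that map to several places are not in the unique counts; overlapping and antisense genes are uncertain too, since the strand setting is not given.

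The comparisons are T-ALL against normal in each organ and spleen against bone marrow in normal and in T-ALL mice. The bone marrow and spleen comparisons of T-ALL share no library, and overlaps are set beside n1 x n2 / N. The comparisons, the size rule, most of the other settings tried and 41 gene lists were fixed before the data were examined. The lists are 5 of macrophages and monocytes, the others for activation, secreted factors, pathways, RNA quality and other cell types. For each list the text gives the members measured, how many were 2-fold higher or lower, the median log2 fold with a bootstrap interval over members (2000 draws), and in places the percentile of that median among 10000 random lists matched on mean expression in 20 bins. The rule for named genes was fixed with them. It takes the 10 highest and 10 lowest genes of each T-ALL comparison, the 8 highest and 8 lowest of each organ comparison, and the 5 strongest opposite changes each way. It adds, per list and comparison, up to 5 members with the largest log2 fold under the size rule, or the member with the highest level where none passed. Predicted and clone-named genes, pseudogenes, antigen receptor segments and sex-linked genes were left out of the top genes, but all of these stay in the counts of genes. Named outside it, after their values were seen, are Cd4, Cd5l, Cd8a, Csf1r, Emr1, Spic and Wif1 in a T-ALL comparison and the shared rises and falls. So are Lyz2 and Csf1r beside the list shares, and Csf1r and Emr1 between the T-ALL organs.

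The other settings tried were total-count and median-of-ratios scaling, pseudocounts of 0.1 and 5, no minimum and minimums of 1 and 50 CPM, the deposited RPKM with a minimum of 5 RPKM, TMM scaling without genes of other cells, immunoglobulins and haemoglobins, and thresholds of 1.5-fold and 4-fold. Added after seeing the data were folds set against the median of the macrophage core list, and counts without the genes of other cell types and sex-linked genes. The size rule was tested on simulated counts from the real library sizes. In the bone marrow comparison it called 100 of 100 genes changed 3-fold, 100 of 100 changed 8-fold and 0 of 9330 unchanged genes, and in the spleen comparison 100 of 100, 100 of 100 and 0 of 9262. The changed genes were drawn only from genes with a mean well above the 10 CPM minimum, and scaling was by total counts. This simulation holds counting error alone, which is small at such levels, so it checks that the rule runs as written and no more.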

Results

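Macrophages were sorted from the bone marrow and the spleen of C57BL/6J mice, and their RNA was sequenced. The mice were either normal, at day 0, or carried T cell acute lymphoblastic leukaemia (T-ALL) at day 21 after a transplant of GFP-labelled leukaemia cells, given without irradiation. The design asks how macrophages in leukaemia, called leukaemia-associated macrophages by the submitters, differ from those of homeostasis, and it holds 4 libraries, 1 for each combination of organ and condition. A uniquely mapped read was counted for 17008 genes in any library and for 13692 genes in all 4. With 1 library per group there were no replicates, so no difference has a replicate check and no p-value is given. Levels are CPM, reads per gene relative to the scaled total of the library, and the pair of values in parentheses after a fold is its 95% counting interval, which covers counting error alone. A gene is called higher or lower where it differed by at least 2-fold on log2(CPM + 1), with 10 CPM or more in the higher library.

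RNA of other cell types was measured in all 4 libraries. The genes of neutrophil precursors took 4.24% (4.22 to 4.25) of the reads of the normal bone marrow library, 2.31% (2.30 to 2.32) of the T-ALL bone marrow library, 0.0555% (0.0540 to 0.0571) of normal spleen and 0.0246% (0.0237 to 0.0257) of T-ALL spleen, with Wilson 95% intervals. The genes of most mouse macrophages took 0.612% (0.607 to 0.617), 1.36% (1.35 to 1.36), 0.969% (0.963 to 0.975) and 0.579% (0.574 to 0.584) in the same order. T cell genes took 0.0291% (0.0281 to 0.0302), 0.0947% (0.0927 to 0.0967), 0.163% (0.16 to 0.165) and 0.438% (0.434 to 0.442). Single genes weigh heavily in such shares. Of the macrophage list's 13675 CPM in T-ALL bone marrow, Lyz2 made up 5494 CPM, and it was at 946 CPM in normal spleen. Csf1r, of the same list, ran the other way, at 947 and 2415 CPM. The macrophage share is thus no measure of macrophage content by itself. The libraries also differed in sex-linked transcripts. Xist, the transcript of the inactive X chromosome of females, was at 861 CPM in normal bone marrow and 849 CPM in normal spleen, against 0.644 CPM in T-ALL bone marrow and 416 CPM in T-ALL spleen. The Y-linked Ddx3y had 0 reads in both normal libraries, which allows up to 3 reads, and 874 and 532 reads in the T-ALL bone marrow and spleen libraries. Eif2s3y, Kdm5d and Uty, also Y-linked, had at most 1 read in each normal library and between 135 and 659 reads in the T-ALL libraries. Sex-linked transcripts thus moved with condition in both T-ALL comparisons.

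**Figure D1:**
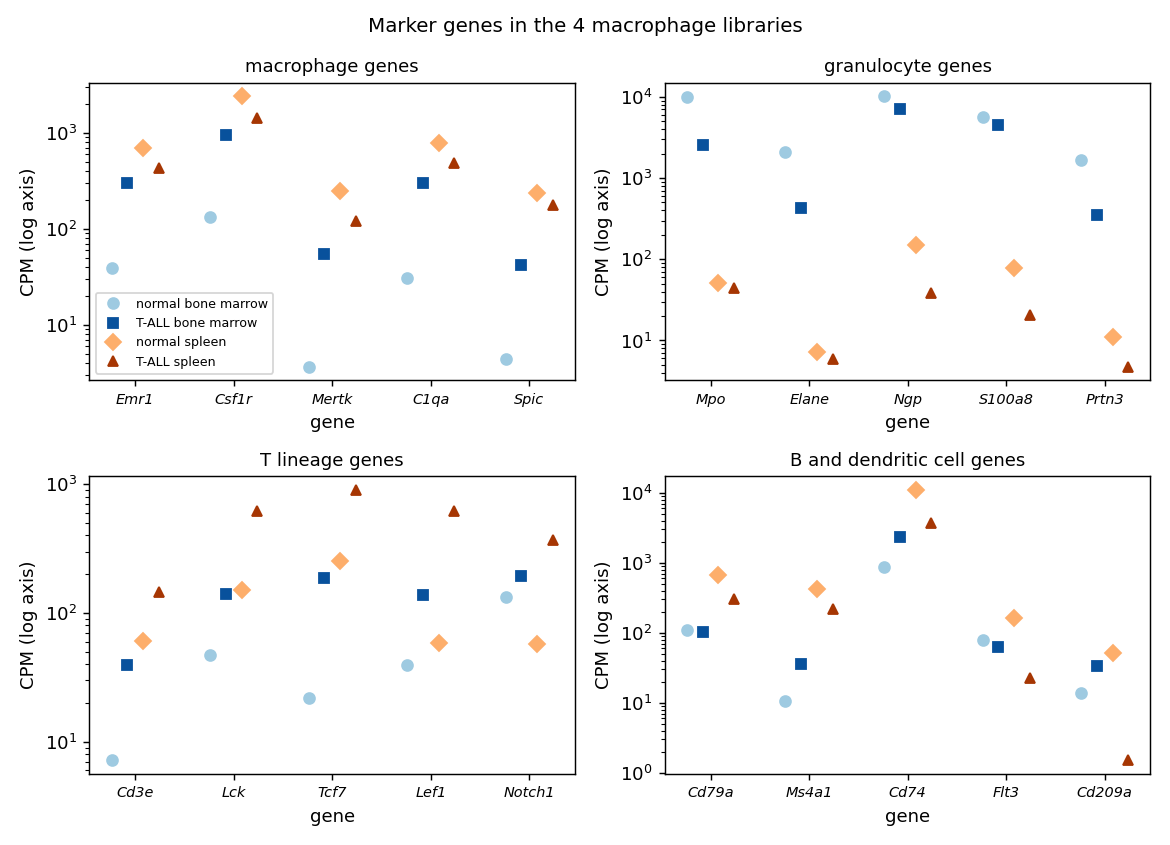
CPM on a log axis of 20 marker genes in the 4 libraries, with 1 point per library and gene. Csf1r was at 133 CPM in normal bone marrow and 947 CPM in T-ALL bone marrow, Mpo at 9900.0 and 2531 CPM, and Lef1 at 58.3 CPM in normal spleen and 617 CPM in T-ALL spleen.

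**Figure D2:**
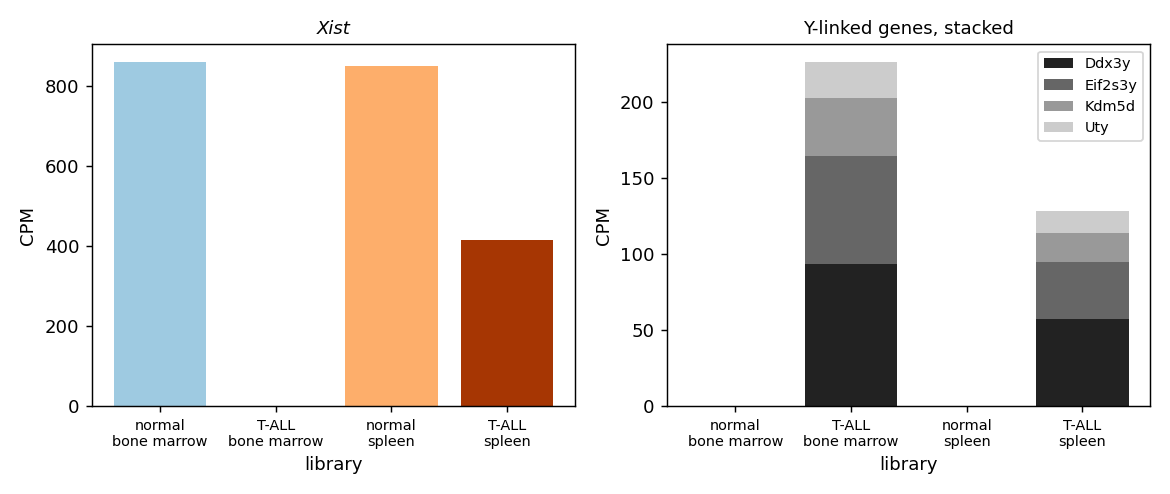
CPM of Xist (left) and of 4 Y-linked genes stacked on each other (right) in the 4 libraries, with bars from 0. The Y-linked genes summed to 227 CPM in T-ALL bone marrow and 129 CPM in T-ALL spleen.

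In bone marrow, macrophage genes were far higher in the T-ALL library and granule genes of neutrophil precursors were lower. Of the 16 measured genes of most mouse macrophages, 13 were at least 2-fold higher and 0 lower, with a median log2 fold of 2.31 (1.11 to 2.72, bootstrap over genes). Emr1, which encodes the macrophage antigen F4/80, went from 39.5 to 304 CPM, 7.69-fold higher (6.91 to 8.57). Csf1r, the receptor for macrophage colony-stimulating factor, was 7.11-fold higher (6.71 to 7.54), and Mertk, a receptor for dying cells, 14.9-fold higher (10.6 to 21.5). Mpo, Elane and Prtn3, which encode enzymes of neutrophil granules, were 3.91-fold (3.86 to 3.97), 4.85-fold (4.69 to 5.02) and 4.72-fold (4.55 to 4.90) lower. Across the 9716 genes measured, 778 were at least 2-fold higher and 100 lower.

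Genes of resident macrophages and of monocytes were among those higher. Of 16 genes of red pulp and erythroblastic island macrophages, 15 were higher (median log2 fold 3.02, 2.22 to 3.24). Among them, Cd5l, secreted by tissue macrophages, went from 9.94 to 191 CPM, C1qa from 30.7 to 303 CPM and Siglec1, a sialic acid receptor, from 15.1 to 168 CPM. Of 6 marginal zone macrophage genes matched, only 2 were measured here, Siglec1 and Nr1h3, and both also stand in other lists. Both passed 2-fold, with Nr1h3 6.87-fold higher (5.18 to 9.24). Of 13 genes of Ly6C-high monocytes, 7 were higher (median 1.74, -0.18 to 2.34), with Fn1 (fibronectin) 15.2-fold higher (14.0 to 16.5), Ccr2, the receptor that guides monocytes, 5.03-fold higher (4.72 to 5.37), and Vcan 14.9-fold higher (10.6 to 21.6). Of 11 Ly6C-low monocyte genes, 9 were higher, including Nr4a1 at 7.16-fold (6.64 to 7.74) and Cx3cr1 at 6.82-fold (6.09 to 7.66). The medians of these 4 lists and of the core list lay at percentile 99.98 or above among 10000 random lists matched on expression.

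Some genes of both classical (M1) and alternative (M2) activation were higher in the T-ALL bone marrow library. No list described in this paragraph had a median log2 fold above that of the macrophage core list, 2.31. The rises therefore do not separate activation from a larger share of macrophage RNA. Of 14 measured M1 genes, 11 were higher and 0 lower (median log2 fold 1.82), among them the cytokine Il1b at 8.09-fold (6.92 to 9.50), Cd86 at 6.86-fold (5.11 to 9.37) and the transcription factor Irf5 at 4.88-fold (4.37 to 5.46). Of 13 M2 genes, 6 were higher and 1 was lower (median 0.63, -0.21 to 2.67). The higher ones included Mrc1, the mannose receptor, at 11.2-fold (9.91 to 12.7), the scavenger receptor Cd163 at 8.65-fold (7.40 to 10.2) and Msr1 at 10.8-fold (7.67 to 15.7). Of 11 chemokines, 7 were higher, and Cxcl2, which attracts neutrophils, went from 1.01 to 33.2 CPM. Ccl6 was 7.43-fold higher (6.71 to 8.25) and Ccl2, which attracts monocytes, 11.4-fold higher (5.76 to 25.7). Igf1 (11-fold, 8.05 to 15.3) and Il18 (5.35-fold, 3.72 to 7.88) were among the 5 of 11 cytokines and growth factors that were higher. Proteases and angiogenic factors were higher in 9 of 14 and lower in 1, with Thbs1 8.25-fold higher (7.25 to 9.42) and Ctss 6.22-fold higher (5.85 to 6.61).

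Functions of phagocytes went the same way, again with no list median above that of the macrophage core list. Complement genes were higher in 9 of 11, efferocytosis and scavenger receptor genes in 12 of 16, and MHC class II genes in 6 of 9, with none of the 3 lists holding a lower gene. Axl and Lrp1, receptors in the uptake of dead cells, were 8.76-fold (8.05 to 9.55) and 9.93-fold (9.14 to 10.8) higher. Cd74, the invariant chain of MHC class II, went from 867 to 2351 CPM, 2.71-fold higher (2.64 to 2.78). Interferon response genes were higher in 11 of 27 (median log2 fold 0.82), with Mx1 at 4.01-fold (3.17 to 5.14), while MHC class I genes were higher in 0 of 12. Immediate early and heat shock genes, which sorting can induce, were higher in 13 of 18, with Atf3 at 10.4-fold (8.84 to 12.3) and Junb at 4.44-fold (4.22 to 4.67).

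Genes of other cell types moved with these changes. Neutrophil precursor genes were lower in 9 of 16 (median log2 fold -1.03), whereas mature neutrophil genes were higher in 6 of 13 and lower in 0, with Retnlg 8.70-fold higher (7.90 to 9.60) and Mmp8 7.54-fold higher (6.81 to 8.36). The summed reads of the mature neutrophil list did not rise, at 1.61% of the normal and 1.45% of the T-ALL library. T cell genes were higher in 14 of 16 (median 1.79), with Cd3e going from 7.20 to 39.7 CPM and Tcf7 from 21.9 to 188 CPM. Genes of thymocytes and T-ALL cells were higher in 7 of 15, and Dtx1, a target of Notch signalling, went from 3.55 to 146 CPM. In the normal spleen library Dtx1 was at 320.5 CPM, so its level alone does not mark leukaemia cells here. B cell genes were higher in 4 of 14 with a median of 0.11, and the B cell precursor genes Vpreb1 and Igll1 were 4.41-fold (3.40 to 5.78) and 3.40-fold (2.84 to 4.09) lower. Basophil and mast cell genes were lower in 3 of 7, with Prss34 going from 1412 to 591 CPM. Neither the 28 cell cycle genes (median -0.69, -0.75 to -0.58), the 10 progenitor genes (median -0.48) nor the 5 megakaryocyte genes (median -0.70) held a member past 2-fold. Erythroid genes were higher in 7 of 17, and eosinophil genes in 4 of 10, although haemoglobin and Ear genes have near-identical copies and their unique reads are uncertain.

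The 10 largest rises were those of Dtx1 (Gene ID 14357), Syt13 (Gene ID 80976), Myo5b (Gene ID 17919), Cd5l (Gene ID 11801), Cxcl2 (Gene ID 20310), Col14a1 (Gene ID 12818), Arsi (Gene ID 545260), Fn1 (Gene ID 14268), Fcna (Gene ID 14133) and Fpr1 (Gene ID 14293), with log2 folds from 5.01 to 3.85. Syt13 had 1 read in the normal and 217 reads in the T-ALL library. The rankings of rises and falls leave out sex-linked genes and the other genes barred by the naming rule. Of the sex-linked genes, Ddx3y went from 0 to 93.8 CPM and Xist from 861 to 0.644 CPM, further than any gene ranked in this paragraph. The 10 largest falls were those of Enpep (Gene ID 13809), Elane (Gene ID 50701), Prtn3 (Gene ID 19152), Col1a2 (Gene ID 12843), Vpreb1 (Gene ID 22362), Mpo (Gene ID 17523), Col1a1 (Gene ID 12842), Ms4a3 (Gene ID 170813), Prss57 (Gene ID 73106) and Ctsg (Gene ID 13035), with log2 folds from -2.33 to -1.73. Col1a1 and Col1a2, chains of type I collagen, made up both falling members of the 3 measured stromal and endothelial genes. With folds set against the median of the macrophage core list, an alternative chosen after seeing the data, 29 genes were higher and 9169 lower. A minimum of 50 CPM in place of 10 left 415 higher and 51 lower genes.

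In spleen, T-lineage and cell cycle genes were higher in the T-ALL library, and genes of dendritic cells and MHC class II and part of the macrophage genes were lower. All 28 measured cell cycle genes were at least 2-fold higher (median 3.98-fold; log2 interval 1.90 to 2.13), with Cdk1, which drives entry into mitosis, 6.79-fold higher (5.76 to 8.05) and Top2a going from 145 to 734 CPM. T cell genes were higher in 12 of 18 and lower in 1, with Lef1 10.6-fold higher (9.68 to 11.6), Lck, a kinase of the T cell receptor, 4.06-fold higher (3.82 to 4.31), and Tcf7 3.59-fold higher (3.43 to 3.77). All 11 MHC class II genes were lower (median -1.54), and Cd74 went from 11050.5 to 3669 CPM. In all, 1008 genes were at least 2-fold higher and 1080 lower of the 9774 measured.

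Macrophage genes were lower or under 2-fold, with exceptions. Of 16 core genes, 7 were lower and 0 higher (median -0.78, -1.18 to -0.46), with Lyz2 (lysozyme) 3.92-fold lower (3.74 to 4.11) and Itgam 2.76-fold lower (2.54 to 3.01). Emr1 was at 698 and 429.5 CPM and Csf1r at 2415 and 1421 CPM, both under 2-fold. Of 16 red pulp and island macrophage genes, 7 were lower and 1 higher, the lower among them Cd163 (6.86-fold, 6.19 to 7.62), Siglec1 (4.06-fold, 3.60 to 4.58), the iron exporter Slc40a1 (3.18-fold, 3.08 to 3.28) and the haem-degrading enzyme Hmox1 (2.64-fold, 2.57 to 2.72). In contrast, Cd5l went from 417 to 874 CPM, and Marco, a scavenger receptor of marginal zone macrophages, was 2.73-fold higher (2.40 to 3.10). Siglec1 was the lower and Marco the higher of 3 measured marginal zone genes. Spic, the transcription factor of red pulp macrophages, was at 234 and 179 CPM. Classical monocyte genes were lower in 4 and higher in 2 of 12, with Ccr2 6.60-fold lower (5.31 to 8.27) and Vcan 30.0-fold higher (11.4 to 112). Of 11 Ly6C-low monocyte genes, 4 were lower, with Cx3cr1 at 3.88-fold (3.43 to 4.40) and Ace at 4.61-fold (4.32 to 4.91).

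Most of the M1 and M2 genes that passed 2-fold in spleen were lower. M1 genes were lower in 5 of 16 and higher in 0, with Ccl5 4.0-fold lower (3.57 to 4.49) and Irf5 3.04-fold lower (2.83 to 3.28). M2 genes were lower in 4 and higher in 1 of 14. The higher M2 gene was Il10, an anti-inflammatory cytokine, which went from 1.34 to 19.8 CPM, 14.8-fold higher (8.25 to 29.1), while Mrc1 was 2.83-fold lower (2.70 to 2.97). The medians of the M1 list, -0.60, and of the M2 list, -0.51, did not lie below the macrophage core median of -0.78. The falls of these 2 lists therefore do not separate activation from a smaller share of macrophage RNA. Chemokines were higher in 3 (Cxcl2, Ccl4 and Ccl3) and lower in 4 of 9, with Cxcl2 11.6-fold higher (6.97 to 20.7). Interferon response genes were lower in 10 of 29 (median -0.88), with Ifit3 at 4.25-fold (3.42 to 5.32) and Oas2 at 3.64-fold (3.15 to 4.23). Efferocytosis and scavenger genes were lower in 8 and higher in 2 of 14, and Apoe, a carrier of lipids, was 2.60-fold lower (2.53 to 2.68). Of 9 complement genes, 2 were higher and 3 lower. Cfb and C4b were 3.04-fold (2.62 to 3.54) and 2.69-fold (2.15 to 3.40) higher and Cfp was 2.40-fold lower (2.29 to 2.5).

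Some metabolic genes were higher. Glycolysis genes were higher in 7 of 17 and lower in 0, with Ldha 2.90-fold higher (2.79 to 3.02). Oxidative phosphorylation genes had a median log2 fold of 0.72 with 2 of 22 past 2-fold, Atp5b and Cycs. The median of the 37 ribosomal protein genes was 0.32, and 0 of them passed 2-fold.

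Markers of other cells in the spleen libraries moved apart. Dendritic cell genes were lower in 12 of 14 (median -1.80), with Flt3, a growth factor receptor of dendritic cells, 7.19-fold lower (6.21 to 8.36) and Clec9a 9.23-fold lower (6.27 to 14.1). NK cell genes were lower in 7 of 9, with a median of -1.34 that turned to 0.34 with a minimum of 50 CPM. B cell genes were lower in 6 of 15 (median -0.95) and plasmacytoid dendritic cell genes in 4 of 8, where Ccr9 was higher. Thymocyte and T-ALL genes were higher in 11 and lower in 2 of 16, with Endou 32.5-fold higher (25.3 to 42.6), Notch1 6.34-fold higher (5.78 to 6.97) and Tox 7.96-fold higher (6.42 to 9.95). Cd4 was at 256 and 264 CPM, and Cd8a at 92.6 and 38.5 CPM, in the normal and T-ALL libraries. Among progenitor genes, Sox4 went from 12.3 to 149.5 CPM, Myb was 5.81-fold higher (5.25 to 6.44), and Kit was 6.04-fold lower (5.26 to 6.95). Neutrophil precursor and mature neutrophil genes were lower in 7 of 10 and 4 of 6, with the precursor gene Gfi1 higher, from low levels such as 149 CPM of Ngp in normal spleen. The medians were -0.10 for 8 plasma cell genes, of which Sdc1 was higher, and -0.10 for 13 erythroid genes.

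The 10 largest rises in spleen were those of Syt13 (Gene ID 80976), Wif1 (Gene ID 24117), Heyl (Gene ID 56198), Ednra (Gene ID 13617), Gfra1 (Gene ID 14585), Ptpn13 (Gene ID 19249), Tead1 (Gene ID 21676), Mpp4 (Gene ID 227157), Fbln1 (Gene ID 14114) and Smo (Gene ID 319757). Syt13 and Wif1, a secreted inhibitor of Wnt signalling, had 0 reads in the normal library and 1233 and 830 in the T-ALL library, so that they were at least 398-fold higher and at least 268-fold higher, against a floor of 3 reads. Heyl, a Notch target, had 1 and 569 reads, and Smo, the signal transducer of the Hedgehog pathway, went from 5.03 to 186 CPM. As in bone marrow, sex-linked genes were left out of the ranking, such as Ddx3y, which went from 0 to 57.6 CPM. The 10 largest falls were those of Cd209a (Gene ID 170786), Mmp12 (Gene ID 17381), Mycl1 (Gene ID 16918), Flt1 (Gene ID 14254), Tlr11 (Gene ID 239081), Klri1 (Gene ID 503550), Kcnj9 (Gene ID 16524), Gpr4 (Gene ID 319197), Abca9 (Gene ID 217262) and Adam8 (Gene ID 11501), with log2 folds from -4.37 to -2.99. Cd209a, a lectin of dendritic cells, went from 51 to 1.52 CPM. Of the genes called, 48.3% were higher; scaling without genes of other cells moved this to 62.8%, with 1300 higher and 769 lower. With folds set against the macrophage core median, as added for bone marrow, 3431 genes were higher and 211 lower.

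**Figure D3:**
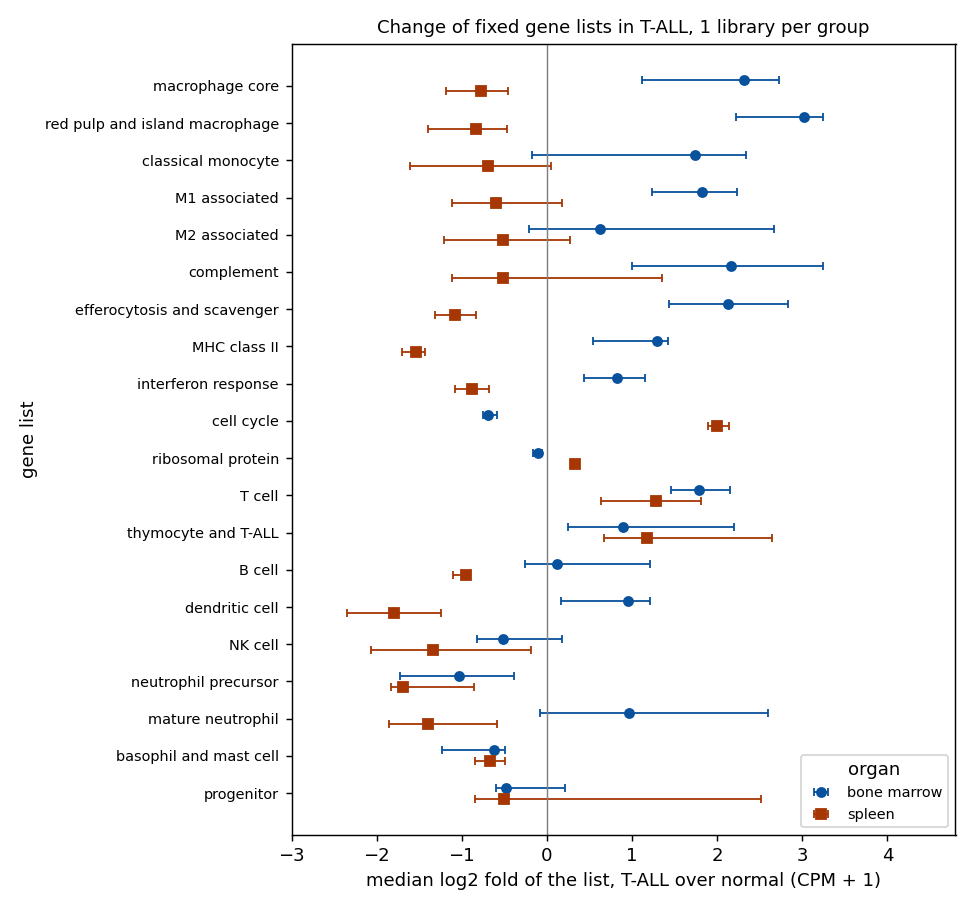
Median log2 fold, T-ALL over normal, of 20 fixed gene lists in bone marrow (circles) and spleen (squares), with bars for the 95% bootstrap interval over list members. The macrophage core median was 2.31 in bone marrow and -0.78 in spleen, and the MHC class II median 1.29 and -1.54.

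At 2-fold, the T-ALL changes of bone marrow and spleen were opposite in 300 genes and alike in fewer; at 4-fold the order turned, with 16 opposite, 27 higher in both and 0 lower in both. Macrophage genes such as Cd163, Siglec1 and Mrc1 were higher in T-ALL bone marrow and lower in T-ALL spleen. Among the 9178 genes measured in both organs, 289 were higher in bone marrow and lower in spleen, where independent lists would share 69.6, and 11 were lower in bone marrow and higher in spleen, where 4.3 would be shared. Across 10312 genes, the log2 folds of the organs had Pearson's r = -0.223 and Spearman's rho = -0.424; genes are not independent replicates. The strongest opposite changes with a rise in bone marrow were those of Col14a1, Cd163, Abca9, Arhgef37 and Ccr3. Ccr3, a chemokine receptor, went from 5.38 to 79.1 CPM in bone marrow and from 349.5 to 86.3 CPM in spleen. Those with a fall in bone marrow were Col1a1, Tuba8, Gfi1, Tmem48 and Poc1a. Gfi1, a transcription factor of granulocytes and lymphocytes, was 2.63-fold lower (2.36 to 2.94) in bone marrow and 3.46-fold higher (2.78 to 4.33) in spleen.

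Other genes moved alike in both organs. There were 82 genes higher in T-ALL in both, where independent lists would share 72.9, and 12 lower in both, where 4.1 would be shared. Syt13, Wif1, Mpp4, Endou, Ptgfrn, Nfib, Dusp4, Camk4, Vcan and Cxcl2 had the largest shared rises, taken by the smaller of their 2 folds and named after their values were seen. Wif1 went from 0.304 to 13.7 CPM in bone marrow and from 0 to 89.9 CPM in spleen, and Endou from 5.17 to 58.9 and from 6.93 to 226 CPM. Prtn3 and Nkg7, a granule protein of cytotoxic cells, were among those lower in both. The r above was -0.104 with a pseudocount of 0.1, and a minimum of 50 CPM left 17 genes higher in both and 168 opposite.

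**Figure D4:**
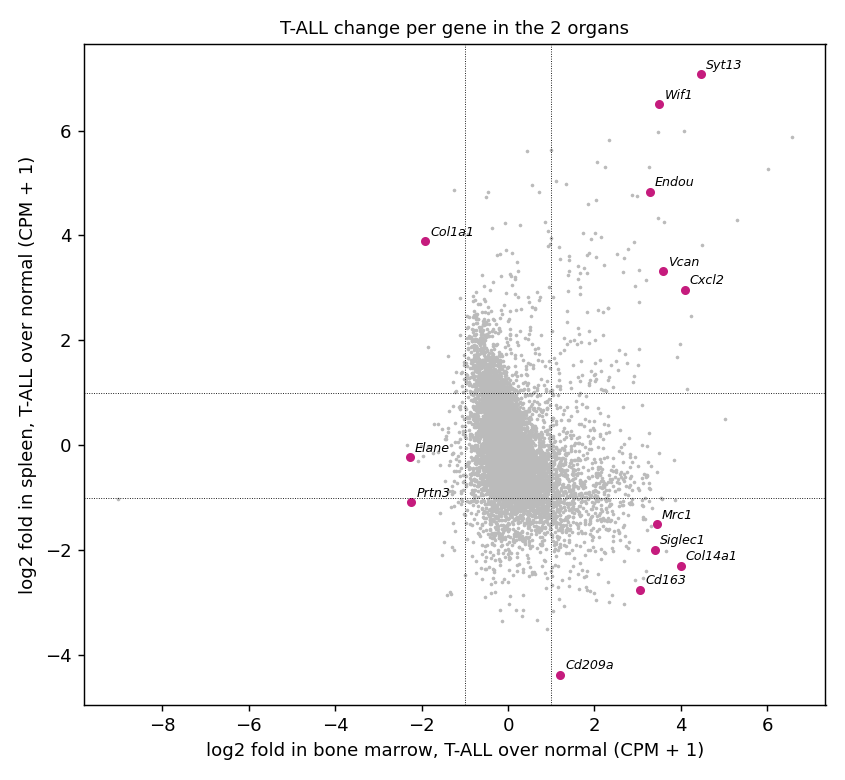
Log2 fold of T-ALL over normal in spleen against that in bone marrow, with 1 point per gene at 10 CPM or more in any library; dotted lines mark 2-fold and named genes are coloured. Cd163 lay at 3.04 in bone marrow and -2.75 in spleen, and the lone point at the far left is Xist.

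Between normal organs, most core macrophage, B cell and MHC class II genes were higher in the spleen library. Most granulocyte, progenitor and cell cycle genes were higher in the bone marrow library. Of 16 core macrophage genes, 12 were higher in spleen and 2 lower. All 16 red pulp and island macrophage genes were higher in spleen (median log2 fold 4.19), with Spic 53.6-fold higher (39.7 to 74.3) and Hmox1 33.0-fold higher (30.3 to 36.0). All 16 neutrophil precursor genes were lower (median -6.01, or -6.16 with the member at 0 reads set to its bound), and Mpo went from 9900.0 CPM in bone marrow to 50.7 CPM in spleen. The 28 cell cycle genes were all lower in spleen (median -2.52), and the 11 MHC class II genes all higher (median 3.63). Of 10072 genes measured, 1626 were higher in spleen and 1413 lower.

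Ly6C-low monocyte genes were higher in spleen in 9 and lower in 1 of 11 (median 2.99), and classical monocyte genes higher in 3 and lower in 7 of 12. Immediate early and heat shock genes, which sorting can induce, were higher in spleen in 13 and lower in 1 of 18 (median 1.79, 1.09 to 2.46), with Egr1 7.08-fold higher (6.63 to 7.56). B cell genes were higher in spleen in 13 and lower in 1 of 15, dendritic cell genes in 14 of 14 and T cell genes in 16 of 18. Basophil and mast cell genes were lower in 7 of 7, and progenitor genes in 7 of 11 with 3 higher, Cd34 being 53.7-fold lower (39.5 to 75.1). The largest rises were those of Cr2 (complement receptor 2, on B cells), C6, Adam23, Adamdec1, Clec4n, Dtx1, Itgad and Kcnj16, with log2 folds from 7.26 to 5.96. The largest falls were those of Elane, Mpo, Prtn3, Ctsg, Ms4a3, Prss34, Mcpt8 and Fcnb, with log2 folds from -7.99 to -6.43. Itgad went from 7.71 to 591 CPM. Of the genes called, 53.5% were higher, against 44.1% when scaled without genes of other cells, with 1386 higher and 1759 lower. A minimum of 50 CPM in place of 10 left 971 higher and 789 lower genes.

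Between the organs of T-ALL mice, granulocyte and classical monocyte genes were lower in spleen, and no cell cycle gene passed 2-fold. Neutrophil precursor genes were lower in spleen in 15 of 16 (median -5.99), mature neutrophil genes in 11 of 13 and classical monocyte genes in 10 of 13. Of 11 Ly6C-low monocyte genes, 3 were lower and 0 higher (median -0.11). S100a8, a calcium-binding protein of neutrophils, went from 4545 CPM in bone marrow to 20.4 CPM in spleen. Of 16 core macrophage genes, 7 were lower in spleen and 2 higher (median -0.39, -1.40 to 0.50), with Lyz2 22.8-fold lower (21.8 to 23.8) and Itgam at 874 CPM in bone marrow and 78.9 CPM in spleen. Core genes thus did not move as a set: Csf1r and Emr1 were higher in spleen, both under 2-fold. The median of the red pulp and island macrophage genes was 0.62, against 4.19 between the normal organs, and that of the cell cycle genes 0.29, against -2.52. T cell genes were higher in spleen in 17 of 18 (median 2.15). Of 9852 genes measured, 536 were higher in spleen and 1086 lower.

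Some macrophage genes differed between the T-ALL organs. Marco was 26.5-fold higher (19.0 to 38.1) in spleen, Cd5l 4.58-fold higher (4.35 to 4.83) and Spic 4.25-fold higher (3.81 to 4.76), whereas Siglec1 was 4.52-fold lower (4.02 to 5.09) and Cd163 3.47-fold lower (3.11 to 3.88). With sex-linked genes again left out, the largest rises were those of C6, Adam23, Cntnap1, Hs3st2, Adamdec1, Cr2, Marco and Dnahc9, with log2 folds from 5.92 to 4.12. Xist, left out, went further, from 0.644 CPM in bone marrow to 416 CPM in spleen. The largest falls were those of Camp, S100a8, S100a9, Ngp, Ltf, Chi3l3, Cd177 and Lcn2, genes of neutrophils and their precursors, with log2 folds from -7.82 to -7.10. Of the genes measured in both organ comparisons, 298 were higher in spleen in normal and in T-ALL mice, where independent lists would share 64.2, and 514 were lower in both, where 142.1 would be shared. A minimum of 50 CPM left 293 higher and 566 lower genes between the T-ALL organs, and a minimum of 1 CPM left 773 and 1687.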

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

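All tests of explanations in this part were chosen after the results were seen.

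The change of T-ALL over normal went opposite ways in the organs for many genes. With 1 library per group the difference between organs was not tested. It was 2-fold or more each way in 289 genes that were higher in bone marrow and lower in spleen, and in 11 genes with the reverse order. The spleen log2 fold minus the bone marrow log2 fold was -6.29 for Col14a1, -5.79 for Cd163, -5.71 for Abca9, -5.66 for Arhgef37 and -5.66 for Ccr3. It was 5.80 for Col1a1, 3.90 for Tuba8, 3.08 for Gfi1, 2.73 for Tmem48 and 2.61 for Poc1a. Among the fixed lists, the medians of MHC class II genes differed by -2.83 and those of efferocytosis and scavenger genes by -3.21, with a rise in bone marrow and a fall in spleen.

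In bone marrow, 13 of 16 macrophage core genes were higher and 9 of 16 neutrophil precursor genes lower in T-ALL. A fall of granulocyte precursors alone would raise the genes of all other cell types alike, but the macrophage core median exceeded the B cell median by 2.20 (0.71 to 2.82), which argues against it as the whole cause. A larger share of macrophages among the sorted cells stays open: the 15 of 16 red pulp and island macrophage genes that were at least 2-fold higher are part of the pattern itself and decide nothing. Of these 16, 10 stand in another list too. It cannot be told apart from a change of expression within macrophages in leukaemia, the study's own contrast, which also stays open, untested.

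In spleen, most T cell genes and all cell cycle genes were higher in T-ALL, and most dendritic cell genes, 6 of 15 B cell genes and 7 of 16 macrophage core genes were lower. More T-lineage cells, leukaemia cells among them, in the sorted cells stay open as a source of the rises, but the 12 of 18 T cell genes at least 2-fold higher are the pattern itself and decide nothing. The sort's markers are not given in the sources used here, so whether it removes such cells is not known. In the normal spleen library, 18 of the 19 T cell genes matched were at 10 CPM or more already, while 2 of the 19 stand in another list. Dilution by this entering RNA alone would lower alike only the genes that the entering cells do not express. The dendritic cell median lay -1.02 (-1.62 to -0.18) from the macrophage core median, the plasma cell median 0.68 (0.30 to 1.15) and the erythroid median 0.68 (0.28 to 1.22) from it. The B cell median lay -0.84 (-1.10 to -0.68) from the plasma cell median and -0.17 (-0.51 to 0.20) from the macrophage core median. Which list members the entering cells express was not measured, and the dendritic cell list itself holds the T cell gene Cd8a. These differences therefore cannot decide on dilution. Dilution as the whole or a part of the cause of the falls stays open, as does a change within the cells of leukaemic spleen, untested.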

How the results depend on the processing

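The folds set against the macrophage core median and the counts without genes of other cells were chosen after seeing the data. Those and the 1.5-fold and 4-fold thresholds are not among the 9 alternatives applied to single genes and lists, which are the scalings, pseudocounts, minimums and RPKM. Of 5553 values of named genes past 2-fold under these 9, 5499 stayed past 2-fold, the other 54 kept their direction, and 0 reversed. A change of minimum cannot move a gene's own fold, so the values under the other minimums stayed by construction. The size of a fold was less stable: 917 of 5688 values of named genes lay outside the counting interval of the reported fold, and 24 of 733 values of list medians outside the bootstrap interval without reversing. The 30 list medians at 2-fold or more gave 267 values under these alternatives, of which 244 stayed so, 21 kept their direction below it and 2 reversed. Without a minimum the spleen median of the stromal and endothelial list was -0.29, and with a minimum of 50 CPM that of the NK cell list was 0.34; both alternatives change which members are measured, from 1 stromal gene under the main rule. Counts of genes under total-read and median-of-ratios scaling, the deposited RPKM and without genes of other cells stayed within 1.5 times those reported, as did those with a pseudocount of 0.1. Scaling without genes of other cells kept counts within that range. It moved the median of all genes by 0.16 in spleen with T-ALL and by -0.16 between normal organs. Between normal organs the larger number then turned from higher to lower, 1386 against 1759. In spleen with T-ALL it turned from lower to higher, with 1300 higher and 769 lower. It turned there too under total reads (1047 and 1034), median-of-ratios (1088 and 983), RPKM (933 and 834) and a pseudocount of 5 (831 and 806). With a pseudocount of 0.1 more genes stayed lower than higher, 1145 and 1050.

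The correlation of the organs' T-ALL changes, -0.223, was -0.104 with a pseudocount of 0.1, -0.322 with 5, -0.181 without a minimum, -0.185 and -0.300 with minimums of 1 and 50 CPM and -0.294 on RPKM; the cause was not tested. A pseudocount of 5, which shrinks low genes, left 7 genes lower in both organs. With no minimum, and alike with 1 CPM, genes lower in T-ALL bone marrow numbered 172, genes lower between T-ALL organs 1687, and 153 were higher and 24 lower in both organs, since more genes are counted. With a minimum of 50 CPM, fewer genes are counted: 415 higher and 51 lower in bone marrow with T-ALL, 605 higher and 566 lower in spleen with T-ALL, 971 higher and 789 lower between normal organs, 293 higher and 566 lower between T-ALL organs, 17 higher in both organs, 4 lower in both and 168 opposite. A threshold of 1.5-fold gave 1369 higher and 689 lower in bone marrow with T-ALL, 1961 higher and 2338 lower in spleen with T-ALL, 2472 higher and 2476 lower between normal organs, 1389 higher and 1879 lower between T-ALL organs, 136 higher in both organs, 55 lower in both and 1075 opposite. One of 4-fold gave 274 higher and 6 lower in bone marrow with T-ALL, 236 higher and 131 lower in spleen with T-ALL, 745 higher and 585 lower between normal organs, 155 higher and 461 lower between T-ALL organs, 27 higher in both organs, 0 lower in both and 16 opposite, so that more genes were alike than opposite. Against the macrophage core median there were 29 higher and 9169 lower genes in bone marrow and 3431 higher and 211 lower in spleen with T-ALL, because that median, 2.31 and -0.78, is taken off every gene. No paired analysis was run. Each group has 1 library, and the sample titles do not say whether bone marrow and spleen came from the same mice. Leaving out a library would leave its group empty.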

Other observations

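The tests of where sex-linked reads come from were chosen after the results were seen. Further fixed lists describe iron, lipids, lysosomes and the restraint of T cells. In bone marrow, iron and haem genes were higher in T-ALL in 8 of 16, lipid handling genes in 11 of 20 and lysosomal genes in 8 of 21, with no member lower. Hmox1 went from 55.5 to 510.2 CPM, Lpl (lipoprotein lipase) from 19.4 to 194 CPM and Psap, a lysosomal cofactor, from 1134 to 4109 CPM. Genes that restrain T cells were higher in 5 of 9, with Cd274, the PD-1 ligand PD-L1, 2.26-fold higher (1.94 to 2.63) and Havcr2 3.47-fold higher (2.63 to 4.64). In spleen, 3 of 12 such genes were lower and 2 higher, with Havcr2 4.88-fold lower (4.23 to 5.66) and Lgals9 (galectin-9) going from 122 to 258 CPM. Iron and haem genes were split there, 3 higher and 3 lower of 17; Tfrc, the transferrin receptor of dividing cells, was 2.43-fold higher (2.26 to 2.61) while Slc40a1 was 3.18-fold lower (3.08 to 3.28). Lipid handling genes were lower in 5 of 19 with 0 higher; of 21 lysosomal genes, 1 was lower, Ctsh, and 1 higher, Gla. MHC class I genes had a spleen median log2 fold of -0.77, with H2-T23 2.06-fold lower (1.94 to 2.20).

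Lists with few changes complete the set. In T-ALL bone marrow, the medians were -0.29 for glycolysis, -0.14 for oxidative phosphorylation and -0.10 for ribosomal proteins, with 0 members past 2-fold. Plasma cell genes were higher in 2 of 7, dendritic cell genes in 3 of 7 and plasmacytoid dendritic cell genes in 1 of 6, and Nkg7 was the lower gene among 8 NK cell genes. B precursor genes were lower in 3 of 9 and higher in 1. In T-ALL spleen, Dntt was the higher gene of 4 B precursor genes, going from 2.01 to 38.9 CPM; it is also a gene of thymocytes. Cytokine genes were higher in 1 and lower in 1 of 11, Il10 and Il15, and proteases and angiogenic factors higher in 1 and lower in 3 of 12, with Mmp12 going from 42.0 to 2.81 CPM. Immediate early and heat shock genes were higher in 2 of 18, Hsph1 and Hspa8. Eosinophil genes were lower in 2 of 4, basophil and mast cell genes in 0 of 2, megakaryocyte genes in 1 of 2 and erythroid genes in 3 of 13. The 1 measured stromal and endothelial gene, Col1a1, went from 0 to 13.9 CPM; without a minimum the list's median was -0.29.

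Y-linked genes summed to 227 CPM in T-ALL bone marrow and 129 CPM in T-ALL spleen, against 0.203 and 0.112 CPM in the normal libraries of these organs, and Xist persisted in T-ALL spleen. In bone marrow, male leukaemia cells among macrophages of female mice would leave Xist, yet it stood at 0.0748% (0.0274% to 0.163%) of its level in the normal library, which argues against that source. In spleen, Xist stood at 49.1% of the normal library and Y-linked reads at 56.7% of the T-ALL bone marrow library. Male leukaemia cells in female mice cannot be told apart there from other mixtures of male and female cells, such as a pool of mice of both sexes. Each predicts Xist beside Y-linked reads. The sample titles do not say whether both T-ALL libraries came from the same mice, so the bone marrow result was not carried over to spleen. Sex and T-ALL are confounded in the 4 libraries, so sex stays among the open explanations of every T-ALL difference, untested.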
